A study of Homo sapiens with 12 samples.

How the data were processed

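RNA abundance was measured on 12 Affymetrix arrays in A431 and HSC-1, established human lines of cutaneous squamous cell carcinoma. Cells received the vehicle DMSO or everolimus, a rapamycin analogue that inhibits mTOR complex 1, at 100 nM for 72 h, with 3 arrays in each of the 4 groups. Group and replicate number were taken from the sample labels. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Per the labels' protocols, total RNA was extracted with TRI reagent, and sense cDNA was made, fragmented and labelled with biotin using GeneChip whole-transcript kits. The labels give the medium with 10 or 20% serum and do not tie either level to a line.

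The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. Their versions, the probe set level and the genome build are not given in the sources used here. RMA places arrays on a common distribution, so a change in total RNA per cell would not be visible in these values. The table held 53617 probe sets on each array, with array medians from 4.34 to 4.39. It carried no detection flags, so a probe set was judged against the median of its own array, and the number of arrays limits the precision. The probe annotation gave 16098 probe sets 1 gene symbol each and left 37519 without a name here. All 16098 were matched by Entrez identifier to the gene table of assembly GRCh38.p14, which was used for current symbols and gene lengths but not for coordinates. The named probe sets covered 14884 genes, of which 779 had several.

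For each gene the probe set with the highest mean over all 12 arrays was used. A gene was tested where at least 3 of the 12 arrays lay above that array's median over all probe sets, which kept 10613 genes (9234 protein coding) and left out 4271. Of the 39 tested genes with several probe sets that changed in A431, 11 had probe sets of opposite sign, as did 27 of 116 in HSC-1. Group means were fitted with lmFit in limma 3.58.1 under R 4.3.3, with moderated variances from eBayes with an intensity trend, 8 residual degrees of freedom and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. The contrasts were everolimus against DMSO in A431, the same in HSC-1, the HSC-1 effect minus the A431 effect, and HSC-1 against A431 in DMSO. Errors of log2 differences are the moderated standard errors (SE), and errors of group means are SDs of 3 arrays.

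Before the data were examined, 29 gene lists were fixed, among them markers of other cell types. The 23 lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the 23 lists, and again with the correlation estimated from the data and with fry. The lists of drug efflux transporters and of replication-dependent histones had 0 named probe sets, and the fibroblast, melanocyte, leukocyte and endothelial markers had 2, 2, 3 and 1 tested members, so these 6 lists were not tested. In each of the 23 tested lists only part of the members was tested, and the results cover that part. It was 46 of 78 for ribosomal proteins, 11 of 35 for translation factors and 7 of 20 for basal keratinocyte genes. The genes named in the text follow a rule set at the same time. It takes, for each comparison, up to 6 rising and 6 falling genes with the largest change past the threshold, with no overlap between the groups' arrays except in the difference between the lines. It adds up to 4 members with the largest change from each list, or the member with the smallest p where none passed, and a fixed panel of mTOR, growth factor and keratinocyte genes. Of that panel, RPTOR, RICTOR, FKBP1A and CDKN1A had no named probe set and are not analysed here.

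The alternatives were a replicate block, no level filter, a stricter one at the 60th percentile of each array, variance priors without the trend or robust, array weights, quantile normalization applied again, median centring, a fit on the 6 arrays of a comparison alone, the mean of a gene's probe sets and leaving out each array. The fit on 6 arrays was not applied to the difference between the lines. A fold threshold of 1.5 and an adjusted p of 0.01 were applied to the gene counts of the 4 comparisons, and an estimated correlation and fry to the lists. The procedure was tested on simulated data with 200 changed genes among 10613. In the simulated A431 comparison 38.8% of genes changed by 0.3 on the log2 scale were recovered, 83.6% at 0.5 and 92.4% at 1, with 7.74% of calls false. In the simulated HSC-1 comparison the shares were 38.8%, 80.6% and 100%, with 5.81% of calls false. Camera called the 1 list shifted in the simulation and 0 of the 22 others. The simulated genes varied independently of each other, so this does not test camera where the genes of a list are correlated. In the data the estimated correlation was 0.18 for the G2/M and mitosis list. Figures were drawn with matplotlib 3.10.9.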

Results

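Expression was measured on 12 arrays, 3 in each of 4 groups: A431 with DMSO, A431 with everolimus, HSC-1 with DMSO and HSC-1 with everolimus. The study's title concerns genes tied to everolimus resistance in cutaneous squamous cell carcinoma, and its design compares each line with and without 100 nM everolimus for 72 h. The labels do not say which line is resistant. Arrays of the same group correlated at 0.989 to 0.992 over all probe sets, arrays of the same line under the other treatment at 0.987 to 0.991, and arrays of different lines at 0.955 to 0.962. Over the tested genes, the first principal component held 85.7% of the variance. The median SE of a log2 difference was 0.09 for a comparison of 3 arrays with 3, and 0.13 for the difference between the lines.

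In A431, SPRR1A and KLK13 had the largest falls after everolimus among the genes past the threshold. SPRR1A (probe set 16671104), a cross-linked precursor of the cornified envelope, had a level of 6.07 ± 0.14 in DMSO and 4.71 ± 0.25 in everolimus (SD, n = 3), a log2 difference of -1.37 ± 0.11 (SE) or 2.58-fold lower (limma adjusted p = 4.3e-07). KLK13 (16874765), an epidermal serine protease, changed by -1.31 ± 0.12, SPRR1B (16671115) by -1.30 ± 0.17 and S100A7 (16693427), the antimicrobial protein psoriasin, by -1.29 ± 0.14. SPRR1B lay below the array median on all 6 A431 arrays and S100A7 on the 3 with everolimus, so the sizes of these differences depend on the background. GPR15LG, a ligand of the receptor GPR15, fell 2.30-fold, and PIGR, which carries polymeric immunoglobulins across epithelia, fell 2.27-fold. The largest rises were smaller. AMIGO2, a cell adhesion protein, rose 1.83-fold (0.87 ± 0.09, limma adjusted p = 4.7e-06). AMTN rose 1.75-fold, the prostacyclin synthase PTGIS 1.66-fold, the iron-binding surface protein MELTF 1.63-fold, ANTXR1 1.59-fold and TTN 1.57-fold. The TTN call was lost with the mean of its probe sets (log2 difference 0.30, limma adjusted p = 0.0872, the highest of all alternatives, which began at 0.00043).

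Of the 30 keratinocyte differentiation genes tested in A431, 14 fell, 1 rose and 15 did not pass, with a median log2 difference of -0.26. Adjusted over the list alone, 17 fell and 1 rose. The list passed with camera (adjusted p = 1.3e-14, and adjusted p = 0.00137 with an estimated correlation). S100A8, a calcium-binding alarmin, fell by 0.89 ± 0.08. Among 7 basal keratinocyte and adhesion genes, 2 fell, among them the basal keratins KRT15 (-0.52 ± 0.04) and KRT14 (-0.29 ± 0.04), and 2 rose (the same counts adjusted over the list alone). This list did not pass (camera adjusted p = 0.534), and KRT5, the partner keratin of KRT14, had a difference of -0.02 ± 0.05 (limma adjusted p = 0.876).

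Cytosolic ribosomal protein transcripts rose in A431. Of 46 tested, 22 rose, 0 fell and 24 did not pass, with a median of 0.19 and 43 positive differences, and 29 rose adjusted over the list alone. Camera gave an adjusted p of 6.4e-21, and an adjusted p = 0.00503 with an estimated correlation. RPS16 rose by 0.43 ± 0.08, RPS14 by 0.37 ± 0.08 and RPL26 by 0.35 ± 0.05. RPS6, whose protein is phosphorylated downstream of mTOR, rose by 0.23 ± 0.05 (limma adjusted p = 0.0134), a call that was lost with a replicate block (0.0576), without A431 DMSO replicate 2 (0.0633) and without A431 everolimus replicate 2 (0.0564), in a range from 0.00721 over all alternatives. The elongation factors EEF1G (0.34 ± 0.05) and EEF2 (0.17 ± 0.03, adjusted p = 0.0812 without the intensity trend, in a range from 0.00126) and the initiation factor EIF4B (0.33 ± 0.04) were the 3 of 11 translation factors that rose, with 0 falling and the same counts adjusted over the list alone. That list passed with camera at an adjusted p of 0.0408, and had an adjusted p = 0.163 with an estimated correlation. Its call was also lost without A431 DMSO replicate 1 (0.0817) and without A431 everolimus replicate 3 (0.127), where its median was -0.025, in a range from 0.0168 to 0.163 over all alternatives. Of all 24 alternatives, 8 lost this call. Of 24 ribosome biogenesis genes, 1 rose, the 60S assembly factor NIP7 (0.24 ± 0.04), 0 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.00753, and adjusted p = 0.0875 with an estimated correlation).

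Of 15 fatty acid synthesis genes in A431, 5 fell, 0 rose and 10 did not pass, with a median of -0.17. Falls numbered 8 adjusted over the list alone (camera adjusted p = 2.9e-08, and adjusted p = 0.00503 with an estimated correlation). ACSL1, which activates long-chain fatty acids, fell by 0.92 ± 0.09, the desaturase SCD by 0.58 ± 0.05, the lipogenic transcription factor SREBF1 by 0.57 ± 0.07 and the acetyl-CoA synthetase ACSS2 by 0.44 ± 0.08. Of 18 glycolysis and hypoxia genes, 3 fell, 0 rose and 15 did not pass, with a median of -0.13. Falls numbered 4 adjusted over the list alone (camera adjusted p = 0.000253, and adjusted p = 0.0142 with an estimated correlation). DDIT4, an inhibitor of mTOR complex 1 induced by stress, fell by 0.57 ± 0.04, the angiogenic growth factor VEGFA by 0.30 ± 0.06 and the glycolytic enzyme GPI by 0.17 ± 0.04. The GPI call was lost without the intensity trend (limma adjusted p = 0.101, in a range from 0.00346). Of 10 NRF2 and oxidative stress genes, 4 fell and 1 rose, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000246, and adjusted p = 0.0714 with an estimated correlation). UGDH, which makes UDP-glucuronate, fell by 0.37 ± 0.05, and the heme-degrading HMOX1 by 0.47 ± 0.13, with a limma adjusted p of 0.0393. The HMOX1 call was lost without A431 DMSO replicate 1 (0.15) or 3 (0.169), A431 everolimus replicate 1 (0.0512) or 2 (0.193) and HSC-1 DMSO replicate 1 (0.0517), in a range from 0.00788 over all alternatives. In total 8 of 22 alternatives lost it.

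Of 30 lysosome and autophagy genes in A431, 4 fell and 0 rose, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0408, and adjusted p = 0.383 with an estimated correlation). The list's call was also lost without A431 DMSO replicate 1 (0.129) and A431 everolimus replicates 2 (0.105) and 3 (0.0650), in a range from 0.00904 over all alternatives. In total 8 of 24 alternatives lost it. The protease CTSS fell by 0.95 ± 0.11, and PSAP and CTSD, a saposin precursor and an aspartic protease, fell by 0.20 ± 0.03 and 0.19 ± 0.04. The CTSD call was lost without the intensity trend (adjusted p = 0.0919, in a range from 0.000131). Of 26 G1/S and DNA replication genes, 2 rose, 0 fell and 24 did not pass (2 rose adjusted over the list alone), with a median of 0.04 (camera adjusted p = 0.00714, and adjusted p = 0.163 with an estimated correlation). The risers were the replication factor GINS2 (0.34 ± 0.06) and cyclin CCNE1 (0.29 ± 0.08, limma adjusted p = 0.0373). The CCNE1 call was lost without A431 DMSO replicate 1 (0.15) or 2 (0.0908), A431 everolimus replicate 1 (0.103) or 3 (0.142) and HSC-1 DMSO replicate 1 (0.0531), in a range from 0.0221 over all alternatives. Altogether 9 of 22 alternatives lost it. Of 34 G2/M and mitosis genes, 2 rose, the proliferation marker MKI67 (0.16 ± 0.04) and the phosphatase CDC25B (0.14 ± 0.04), 0 fell and 32 did not pass. Adjusted over the list alone 1 rose, and camera gave an adjusted p of 0.000304, and an adjusted p = 0.313 with an estimated correlation. The MKI67 call was lost without A431 DMSO replicate 2 (limma adjusted p = 0.0545), in a range from 0.00316 to 0.106 over all alternatives. The CDC25B call was lost without each array except HSC-1 everolimus replicate 3, at up to 0.181 without A431 everolimus replicate 2, in a range from 0.0153 over all alternatives. Of 22 alternatives each, 2 lost the MKI67 call and 15 the CDC25B call.

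Among the fixed panel in A431, MTOR rose by 0.25 ± 0.05 (limma adjusted p = 0.00245) and MYC by 0.23 ± 0.05, while EGFR (-0.01 ± 0.03), IRS2 (0.10 ± 0.09) and CCND1 (-0.04 ± 0.04) did not pass. Of 17 ERK output genes, 3 rose, among them the phosphatase DUSP6 (0.40 ± 0.07), and 2 fell, among them the immediate-early factor EGR1 (-0.58 ± 0.07), with 4 and 2 adjusted over the list alone. That list did not pass (camera adjusted p = 0.534), and its median and mean differed in sign. Nucleotide synthesis genes rose in 3 of 24 and fell in 2, and in 6 and 7 adjusted over the list alone (median 0.07, camera adjusted p = 0.409). Amino acid response genes fell in 2 of 26 and rose in 0, and in 2 and 1 adjusted over the list alone (median -0.0019, camera adjusted p = 0.625). Receptor, IRS and FOXO feedback genes rose in 1 of 20 and fell in 2, and in 2 and 2 adjusted over the list alone (median -0.04, camera adjusted p = 0.834). Cytokine genes rose in 2 of 14 and fell in 1, and in 2 and 2 adjusted over the list alone (median 0.03, camera adjusted p = 0.580). In all, 714 of 10613 genes changed in A431, 254 up and 460 down, and 2030 had an unadjusted p under the same 0.05. Of the 714, 66 changed at least 1.5-fold, 9 up and 57 down. The total was 458 without A431 DMSO replicate 1, 456 without A431 DMSO replicate 2 and 438 without the intensity trend. The 3 everolimus arrays lay wholly on one side of the 3 DMSO arrays for 24.5% of genes, against 10% by chance. Of the 714 genes, 3 lay below the array median on all 6 A431 arrays.

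In HSC-1, the alarmins S100A8 and S100A9 fell most. S100A8 (16693414) went from 8.70 ± 0.04 to 6.73 ± 0.10 (SD, n = 3), a log2 difference of -1.97 ± 0.08 or 3.91-fold lower (limma adjusted p = 1.55e-11), and S100A9 (16671139) was 3.06-fold lower (-1.61 ± 0.08). GNE, which starts sialic acid synthesis, fell 2.93-fold, the lysosomal membrane protein LAPTM5 2.81-fold, the secreted glycoprotein STC1 2.81-fold and CLCA2, a regulator of chloride conductance in squamous epithelium, 2.61-fold. F2RL2, the thrombin receptor PAR3, rose 2.65-fold (1.40 ± 0.20, limma adjusted p = 5.8e-05), the matrix protein MXRA5 2.35-fold, NOP53, a factor in ribosome assembly, 2.06-fold and CREBRF, a regulator of a membrane-bound stress transcription factor, 2.05-fold. The probe sets of the microRNA genes MIR3671 and MIR23B rose 2.77-fold and 2.12-fold, and the array does not separate a mature microRNA from a longer transcript. MIR3671 lay below the array median on the 3 HSC-1 arrays with DMSO.

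Cell cycle transcripts fell in HSC-1. Of 34 G2/M and mitosis genes, 27 fell, 0 rose and 7 did not pass, with a median of -0.27. There were 28 falls adjusted over the list alone (camera adjusted p = 9.0e-17, and adjusted p = 0.0251 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell by 0.54 ± 0.04, the mitotic kinase PLK1 by 0.51 ± 0.04, cyclin CCNB1 by 0.45 ± 0.06 and cyclin CCNA2 by 0.45 ± 0.04. Of 26 G1/S and DNA replication genes, 21 fell, 1 rose and 4 did not pass, with a median of -0.28. Adjusted over the list alone 22 fell and 1 rose (camera adjusted p = 2.5e-11, and adjusted p = 0.00837 with an estimated correlation). The replication initiation factors MCM10 and CDC6 fell by 0.57 ± 0.07 and 0.55 ± 0.06.

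Ribosomal protein transcripts rose in HSC-1 as well, and ribosome biogenesis transcripts fell. Of 46 ribosomal protein genes, 25 rose, 0 fell and 21 did not pass, with a median of 0.23 (camera adjusted p = 5.5e-18, and adjusted p = 0.00837 with an estimated correlation). Adjusted over the list alone, 30 rose and 1 fell. RPS18 rose by 0.55 ± 0.07, RPL10 by 0.47 ± 0.04 and RPS6 by 0.41 ± 0.05. EEF1G rose by 0.65 ± 0.05, EIF4B by 0.55 ± 0.04 and EEF2 by 0.34 ± 0.03, but of 11 translation factors 3 rose and 2 fell (4 and 3 adjusted over the list alone), the list did not pass (camera adjusted p = 0.148) and its median and mean differed in sign. Of 24 ribosome biogenesis genes, 12 fell, 1 rose and 11 did not pass, with a median of -0.22. Adjusted over the list alone 16 fell and 1 rose (camera adjusted p = 5.9e-07, and adjusted p = 0.00837 with an estimated correlation). The nucleolar protein LYAR fell by 0.66 ± 0.09 and the rRNA methyltransferase NOP2 by 0.48 ± 0.06.

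Of 26 amino acid response and tRNA synthetase genes in HSC-1, 14 fell, 0 rose and 12 did not pass, with a median of -0.17. There were 15 falls adjusted over the list alone (camera adjusted p = 2.1e-06, and adjusted p = 0.0316 with an estimated correlation). PSAT1, of serine synthesis, fell by 0.77 ± 0.04, the asparagine synthetase ASNS by 0.43 ± 0.05 and the pseudokinase TRIB3 by 0.35 ± 0.07. Of 24 pentose phosphate and nucleotide synthesis genes, 6 fell and 0 rose, and 11 fell adjusted over the list alone (camera adjusted p = 0.0124, and adjusted p = 0.190 with an estimated correlation). The mitochondrial serine hydroxymethyltransferase SHMT2 fell by 0.36 ± 0.08 and the ribonucleotide reductase subunit RRM2 by 0.34 ± 0.05. Of 18 glycolysis and hypoxia genes, 6 fell and 0 rose, and 7 fell and 2 rose adjusted over the list alone, with TPI1 (-0.53 ± 0.13), DDIT4 (-0.38 ± 0.04) and LDHA (-0.37 ± 0.07) among the falls (camera adjusted p = 0.0154, and adjusted p = 0.0505 with an estimated correlation). Of 15 fatty acid synthesis genes, 4 fell and 0 rose, the same counts adjusted over the list alone, and the list did not pass (median -0.08, camera adjusted p = 0.127).

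The ERK output list and the inflammatory cytokine list were lower in HSC-1 as lists, though most members of each did not pass. Of 17 ERK output and EGFR ligand genes, 6 fell, 0 rose and 11 did not pass, with a median of -0.23. With the p adjusted over the list alone 6 fell and 1 rose (camera adjusted p = 0.00154, and adjusted p = 0.0292 with an estimated correlation). EGR1 fell by 1.00 ± 0.07, the AP-1 subunit FOSL1 by 0.97 ± 0.08, the EGFR ligand HBEGF by 0.84 ± 0.09 and IER3 by 0.74 ± 0.05. Of 14 inflammatory cytokine and chemokine genes, 5 fell, 0 rose and 9 did not pass, with a median of -0.20. With the p adjusted over the list alone 7 fell (camera adjusted p = 0.00113, and adjusted p = 0.0251 with an estimated correlation). The interleukin-1 receptor antagonist IL1RN fell by 0.98 ± 0.08, the adhesion receptor ICAM1 by 0.97 ± 0.10 and the lipocalin LCN2 by 0.76 ± 0.08. IL1RN lay below the array median on the 3 HSC-1 arrays with everolimus. Of 30 keratinocyte differentiation genes, 10 fell, 4 rose and 16 did not pass, the same counts adjusted over the list alone, with S100A7 (-1.37 ± 0.14) and SPRR1A (-1.18 ± 0.11) among the falls. That list passed with camera at an adjusted p of 0.00683, and had an adjusted p = 0.0505 with an estimated correlation. Of 7 basal keratinocyte genes, 2 rose and 1 fell, and 3 and 2 adjusted over the list alone (median 0.09, camera adjusted p = 0.137).

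Of 20 growth factor receptor, IRS and FOXO feedback genes in HSC-1, 6 rose, 1 fell and 13 did not pass, the same counts adjusted over the list alone (camera adjusted p = 0.00626, and adjusted p = 0.0316 with an estimated correlation). The insulin receptor substrate IRS2 rose by 0.85 ± 0.09, TXNIP, an inhibitor of thioredoxin and of glucose uptake, by 0.73 ± 0.07 and the receptor FGFR2 by 0.55 ± 0.08, while IRS1 fell by 0.42 ± 0.12, with a limma adjusted p of 0.0239. The IRS1 call was lost without HSC-1 DMSO replicate 1 (0.0513) or 3 (0.119) and HSC-1 everolimus replicate 2 (0.139), in a range from 0.00517 over all alternatives. Altogether 4 of 22 alternatives lost it. Of 30 lysosome and autophagy genes, 9 rose, 3 fell and 18 did not pass, and 13 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.00259, and adjusted p = 0.137 with an estimated correlation). The peptidase TPP1 rose by 0.59 ± 0.06 and the folliculin partner FNIP1 by 0.41 ± 0.065, while CTSS fell by 1.06 ± 0.11. In the fixed panel, EIF4EBP1, a translation repressor phosphorylated by mTOR, fell by 0.37 ± 0.07, CCND1 rose by 0.23 ± 0.04 and KRT14 fell by 0.17 ± 0.04 (adjusted p = 0.0535 without the intensity trend, in a range from 0.000814). EGFR (0.01 ± 0.03), MTOR (0.11 ± 0.05), MYC (0.13 ± 0.05) and KRT5 (0.09 ± 0.05) did not pass, but MYC passed without HSC-1 everolimus replicate 1 (adjusted p = 0.0382, in a range from 0.0183 to 0.3 over all alternatives). MYC did not pass in 19 of 22 alternatives. Neither MTOR nor MYC passed the test of the difference between the lines. For MTOR the limma adjusted p of that difference ran from 0.0862 to 0.364 over its 21 alternatives.

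In all, 1977 of 10613 genes changed in HSC-1, 779 up and 1198 down, and 139 of them at least 1.5-fold, 67 up and 72 down. Among all genes tested, 3187 had an unadjusted p under 0.05. Arrays of both treatments did not overlap for 33.3% of genes, against 10% by chance. Of the 1977 genes, 2 lay below the array median on all 6 HSC-1 arrays. Several lists passed with camera in neither line. Cholesterol synthesis had medians of -0.04 in A431 and -0.00065 in HSC-1 (camera adjusted p = 0.169 and 0.914), oxidative phosphorylation -0.01 and 0.04 (0.715 and 0.710), CDK inhibitors and p53 targets 0.06 and -0.15 (0.534 and 0.278), mTOR pathway components 0.01 and 0.05 (0.798 and 0.810), EMT and extracellular matrix -0.03 and 0.01 (0.534 and 0.710), interferon response -0.01 and -0.07 (0.534 and 0.119) and simple epithelial markers 0.08 and -0.08 (0.625 and 0.157). These values cover 17 of 25 listed cholesterol genes, 13 of 44 for oxidative phosphorylation, 12 of 30 for CDK inhibitors and p53 targets and 18 of 32 for the mTOR pathway. For EMT 12 of 39 were tested, for interferon response 29 of 50 and for simple epithelial markers 5 of 7. In HSC-1 the median and mean of the mTOR pathway and EMT lists differed in sign. The NRF2 list did not pass in HSC-1 (median -0.13, camera adjusted p = 0.0611) but did without HSC-1 everolimus replicate 2 (0.0438), without a level filter (0.0255), with quantile normalization again (0.0369), with median centring (0.0439) and with fry (0.00169). Its range over all alternatives reached 0.234. Of its 10 genes, 4 fell and 1 rose, and 5 and 1 adjusted over the list alone. The difference between the lines did not pass for the NRF2 list (median 0.05, camera adjusted p = 0.505). The simple epithelial list passed without HSC-1 DMSO replicate 3 (0.0492) and with fry (0.0420), in a range to 0.476. Fry, which does not compare a list with other genes, also passed 5 more lists that camera did not in HSC-1. These were EMT (0.0420, in a range to 0.960), interferon response (0.00873, to 0.264), fatty acid synthesis (0.00223, to 0.234), basal keratinocyte (0.000248, to 0.234) and translation factors (0.000860, to 0.303). In A431 it passed the basal keratinocyte list (0.00737, to 0.689).

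**Figure D1:**
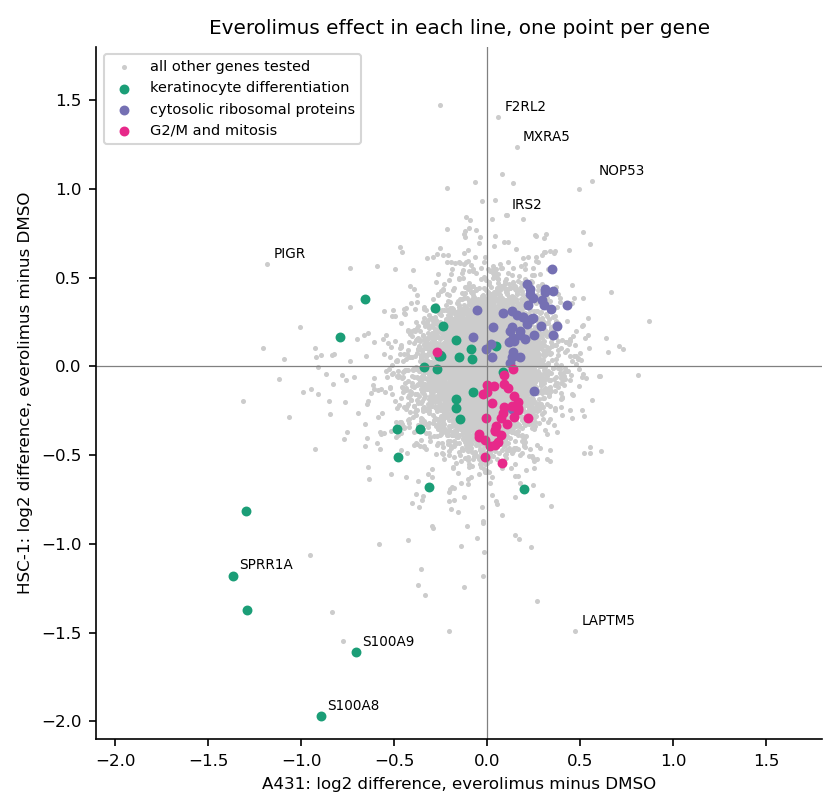
Each point is 1 of 10613 tested genes, with the log2 difference between everolimus and DMSO in A431 on the x axis and in HSC-1 on the y axis, and colours mark 3 gene lists. Ribosomal protein genes lie mostly above 0 on both axes, with medians of 0.19 and 0.23, while G2/M genes lie mostly below 0 in HSC-1, with a median of -0.27, and near 0.07 in A431.

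Calls were shared between the lines more than independent lists would give. In the same direction, 219 genes changed in both lines, 83 up against 18.6 for independent lists (odds ratio 6.74, Fisher's exact test, two-sided, p = 2.5e-33) and 136 down against 51.9 (odds ratio 3.59, p = 6.7e-28). These p-values run across genes, which are not independent replicates. The lines have separate DMSO arrays, so no control is shared, but both comparisons use the same variance estimate for each gene. A gene with a small estimate is called more easily in both lines, so the excess over independent lists may be overstated. With each line fitted on its 6 arrays alone, 191 genes changed in the same direction in both lines. S100A8 fell 1.86-fold in A431 and 3.91-fold in HSC-1, SPRR1A 2.58-fold and 2.26-fold, and EEF1G rose 1.26-fold and 1.57-fold. The shared total was 126 without the intensity trend. In opposite directions, 85 genes changed, 32 up in A431 and down in HSC-1 against 28.7 for independent lists and 53 down in A431 and up in HSC-1 against 33.8. All 85 also passed the test of the difference between the lines, which follows largely from opposite effects adding up in that difference.

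That test, the HSC-1 effect minus the A431 effect, bears on the question of unequal response to everolimus. PIGR had a difference of 1.76 ± 0.18 (limma adjusted p = 5.7e-06): it fell by 1.18 ± 0.13 in A431, while all 6 HSC-1 arrays lay below the array median, so its value there depends on the background. LAPTM5 had a difference of -1.97 ± 0.14 (limma adjusted p = 1.8e-07), with a rise of 0.47 ± 0.10 in A431 and a fall in HSC-1. VGLL1, a cofactor of TEAD transcription factors, fell by 0.74 ± 0.07 in A431 and rose by 0.56 ± 0.07 in HSC-1, and GPR15LG (1.31 ± 0.15) and the diamine oxidase AOC1 (1.23 ± 0.21) were lowered in A431 without passing in HSC-1. The collagenase MMP1 (-1.59 ± 0.22), STC1 (-1.29 ± 0.18) and FOSL1 (-1.15 ± 0.11) were lower in HSC-1 relative to A431. MMP1 and STC1 lay below the array median on all 6 A431 arrays, where a fall could not be seen, so the sizes of these differences depend on the background. F2RL2 (1.34 ± 0.28), MIR3671 (1.72 ± 0.35), the pseudogene LOC440895 (-1.25 ± 0.22) and SNAR-D (-1.16 ± 0.20), a small RNA with near-identical copies whose signals may not be separable, were also past the threshold. LOC440895 lay below the array median on all 6 A431 arrays and on the 3 HSC-1 arrays with everolimus, and MIR3671 on the 3 HSC-1 arrays with DMSO.

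The difference was past the threshold for 1118 genes, 514 higher and 604 lower in HSC-1 relative to A431, and 228 of them differed at least 1.5-fold. Of the 1118 genes, 23 lay below the array median on all 6 arrays of at least 1 line. Of 34 G2/M genes, 25 had a lower effect in HSC-1, 0 a higher one and 9 did not pass, with a median difference of -0.36. With the p adjusted over the list alone 30 were lower (camera adjusted p = 4.9e-21, and adjusted p = 0.0157 with an estimated correlation). Of 26 G1/S genes, 19 were lower and 1 higher, and 23 and 1 adjusted over the list alone (camera adjusted p = 1.0e-13, and adjusted p = 0.00559 with an estimated correlation). CDC20 differed by -0.62 ± 0.06 and GINS2, which rose in A431 and fell in HSC-1, by -0.81 ± 0.08. Of 24 ribosome biogenesis genes, 12 were lower and 0 higher, and 17 lower adjusted over the list alone (camera adjusted p = 2.7e-09, and adjusted p = 0.00559 with an estimated correlation), with NIP7 at -0.47 ± 0.06 and LYAR at -0.67 ± 0.13.

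ERK output genes were lower in HSC-1 relative to A431 in 6 of 17, higher in 0, and lower in 8 and higher in 1 adjusted over the list alone (camera adjusted p = 0.000443, and adjusted p = 0.0221 with an estimated correlation), among them HBEGF (-0.92 ± 0.13) and IER3 (-0.89 ± 0.08). Of 14 cytokine genes, 4 were lower and 0 higher, and 5 lower adjusted over the list alone (camera adjusted p = 9.7e-05, and adjusted p = 0.0149 with an estimated correlation), with ICAM1 at -0.91 ± 0.14. Receptor, IRS and FOXO feedback genes were higher in 6 of 20 and lower in 0, and higher in 6 and lower in 1 adjusted over the list alone (camera adjusted p = 0.00559, and adjusted p = 0.0374 with an estimated correlation), with TXNIP at 0.85 ± 0.09 and IRS2 at 0.75 ± 0.13. Of 7 basal keratinocyte genes, KRT15 (0.40 ± 0.06) and the laminin receptor BCAM (0.40 ± 0.05) were higher and 0 were lower, the same counts adjusted over the list alone (camera adjusted p = 0.00221, and adjusted p = 0.0374 with an estimated correlation).

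The remaining 4 lists that passed for the difference between the lines did not pass with an estimated correlation. Fatty acid synthesis genes were higher in HSC-1 relative to A431 in 5 of 15 and lower in 1, the same counts adjusted over the list alone (camera adjusted p = 0.00941, and adjusted p = 0.0769 with an estimated correlation), with ACSL1 at 0.97 ± 0.12, the fatty acid synthase FASN at 0.52 ± 0.06 and the elongase ELOVL6 at -0.56 ± 0.12. Lysosome genes were higher in 7 of 30 and lower in 0, and higher in 8 adjusted over the list alone (camera adjusted p = 9.7e-05, and adjusted p = 0.0729 with an estimated correlation), with PSAP at 0.53 ± 0.05 and CTSD at 0.46 ± 0.05. Amino acid response genes were lower in 7 of 26 and higher in 0, and lower in 8 adjusted over the list alone (camera adjusted p = 0.000325, and adjusted p = 0.0769 with an estimated correlation), with PSAT1 at -0.83 ± 0.06. Nucleotide synthesis genes were lower in 6 of 24 and higher in 1, and lower in 7 and higher in 1 adjusted over the list alone (camera adjusted p = 0.00725, and adjusted p = 0.168 with an estimated correlation), with CTPS1 at -0.56 ± 0.11. Keratinocyte differentiation did not pass (camera adjusted p = 0.139), with 4 genes higher, among them the mucosal keratins KRT13 (1.03 ± 0.10) and KRT4 (0.96 ± 0.07), and 4 lower, and 5 and 4 adjusted over the list alone. Ribosomal proteins did not pass either (camera adjusted p = 0.139, median 0.04), with 3 of 46 higher and 1 higher adjusted over the list alone. The simple epithelial list did not pass (median -0.13, camera adjusted p = 0.142) but did without HSC-1 DMSO replicate 3 (0.0397), in a range to 0.368 over its alternatives. The median, mean or test of the translation factor, glycolysis and EMT lists differed in sign for this contrast.

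**Figure D2:**
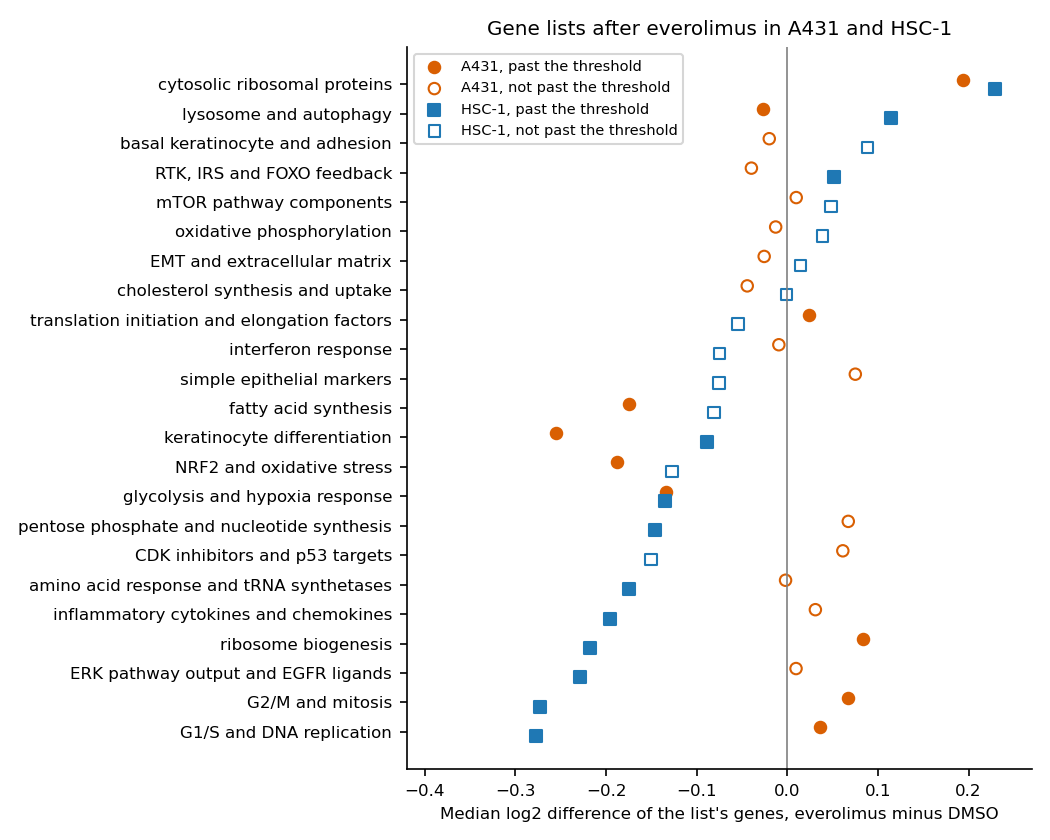
The x axis gives the median log2 difference between everolimus and DMSO over the tested genes of each of 23 lists, with circles for A431 and squares for HSC-1, and filled symbols mark lists past the camera threshold at the preset correlation. The G1/S list lies at -0.28 in HSC-1 and 0.04 in A431, and the ribosomal protein list at 0.23 and 0.19.

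Without everolimus, HSC-1 and A431 differed in 6303 of 10613 genes, 3100 higher and 3203 lower in HSC-1, and 1183 of them at least 2-fold. EDN1, the precursor of endothelin-1, was 45.2-fold higher in HSC-1 (5.50 ± 0.08, limma adjusted p = 5.9e-19), the cytokine IL24 28.0-fold, cyclin CCND2 25.1-fold, the epidermal protease KLK5 21.3-fold, ZNF117 19.8-fold and PASD1 19.0-fold. The adhesion receptor ADGRF1 was 29.7-fold lower (-4.89 ± 0.11, limma adjusted p = 2.7e-17), the antiviral protein BST2 27.3-fold, the lipid transfer protein PLTP 26.5-fold, CYB5A 26.1-fold, the neuropeptide NMU 22.1-fold and the guanylate-binding protein GBP4 22.0-fold. EDN1, IL24, ZNF117 and PASD1 lay below the array median on the 3 A431 arrays, and BST2, CYB5A and GBP4 on the 3 HSC-1 arrays, so the sizes and order of these folds depend on the background. EGFR had a level of 11.64 ± 0.02 in A431 and 12.52 ± 0.03 in HSC-1 (SD, n = 3), 1.84-fold higher in HSC-1. Medium with 10 or 20% serum is not tied to a line in the labels, so whether serum also differed between the lines is not given in the sources used here. Arrays of the lines did not overlap for 65.3% of genes, against 10% by chance. Of the 6303 genes, 354 lay below the array median on all 3 DMSO arrays of at least 1 line.

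Of 29 interferon response genes, 23 were lower in HSC-1, 2 higher and 4 did not pass, with a median of -0.93. With the p adjusted over the list alone 24 were lower and 3 higher (camera adjusted p = 3.8e-06, and adjusted p = 0.0647 with an estimated correlation). IFI44 was 20.9-fold lower and SAMD9L 11-fold lower, with IFI44 below the array median on the 3 HSC-1 arrays. Of 12 EMT and extracellular matrix genes, 8 were higher, 2 lower and 2 did not pass, the same counts adjusted over the list alone, with a median of 1.88 (camera adjusted p = 0.00151, and adjusted p = 0.143 with an estimated correlation). The matrix glycoprotein TNC was 17.9-fold, MMP1 7.89-fold, the collagenase MMP13 7.84-fold and thrombospondin THBS1 4.80-fold higher in HSC-1, with MMP1 below the array median on the 3 A431 arrays. Of 15 fatty acid synthesis genes, 12 were lower and 3 higher, the same counts adjusted over the list alone, with ACSL1 8.18-fold, SCD 3.50-fold and the desaturase FADS1 3.41-fold lower (camera adjusted p = 0.000558, and adjusted p = 0.0647 with an estimated correlation). Of 10 NRF2 genes, 8 were lower and 2 higher, the same counts adjusted over the list alone, with the glutathione peroxidase GPX2 7.80-fold lower (camera adjusted p = 0.0124, and adjusted p = 0.211 with an estimated correlation). Of 24 ribosome biogenesis genes, 15 were higher and 2 lower, and 15 and 3 adjusted over the list alone, with the helicase DDX10 2.52-fold and LYAR 2.48-fold higher (camera adjusted p = 0.00346, and adjusted p = 0.0961 with an estimated correlation).

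Among the fixed panel in DMSO, IRS2 was 3.48-fold, MYC 1.8-fold and KRT14 1.1-fold higher in HSC-1, and CCND1 was 2.52-fold, EIF4EBP1 1.35-fold and MTOR 1.18-fold lower. KRT15 was 5.51-fold lower in HSC-1. KRT5 was 1.09-fold higher (limma adjusted p = 0.0214), a call lost without the intensity trend (0.0838), without A431 DMSO replicate 1 (0.0563) or 2 (0.0585) and without HSC-1 DMSO replicate 1 (0.0763) or 2 (0.0772), in a range from 0.00433 over all alternatives. The amino acid response list did not pass in DMSO (median -0.39, camera adjusted p = 0.0592) but did without HSC-1 DMSO replicate 1 (0.0428), without the intensity trend (0.0478), without a level filter (0.0290) and with fry (1.4e-06), in a range to 0.439. Fry passed 19 lists in DMSO, where camera passed 5. The median, mean or test differed in sign for the translation factor, glycolysis, G1/S, basal keratinocyte and keratinocyte differentiation lists, of which 0 passed.

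**Figure D3:**
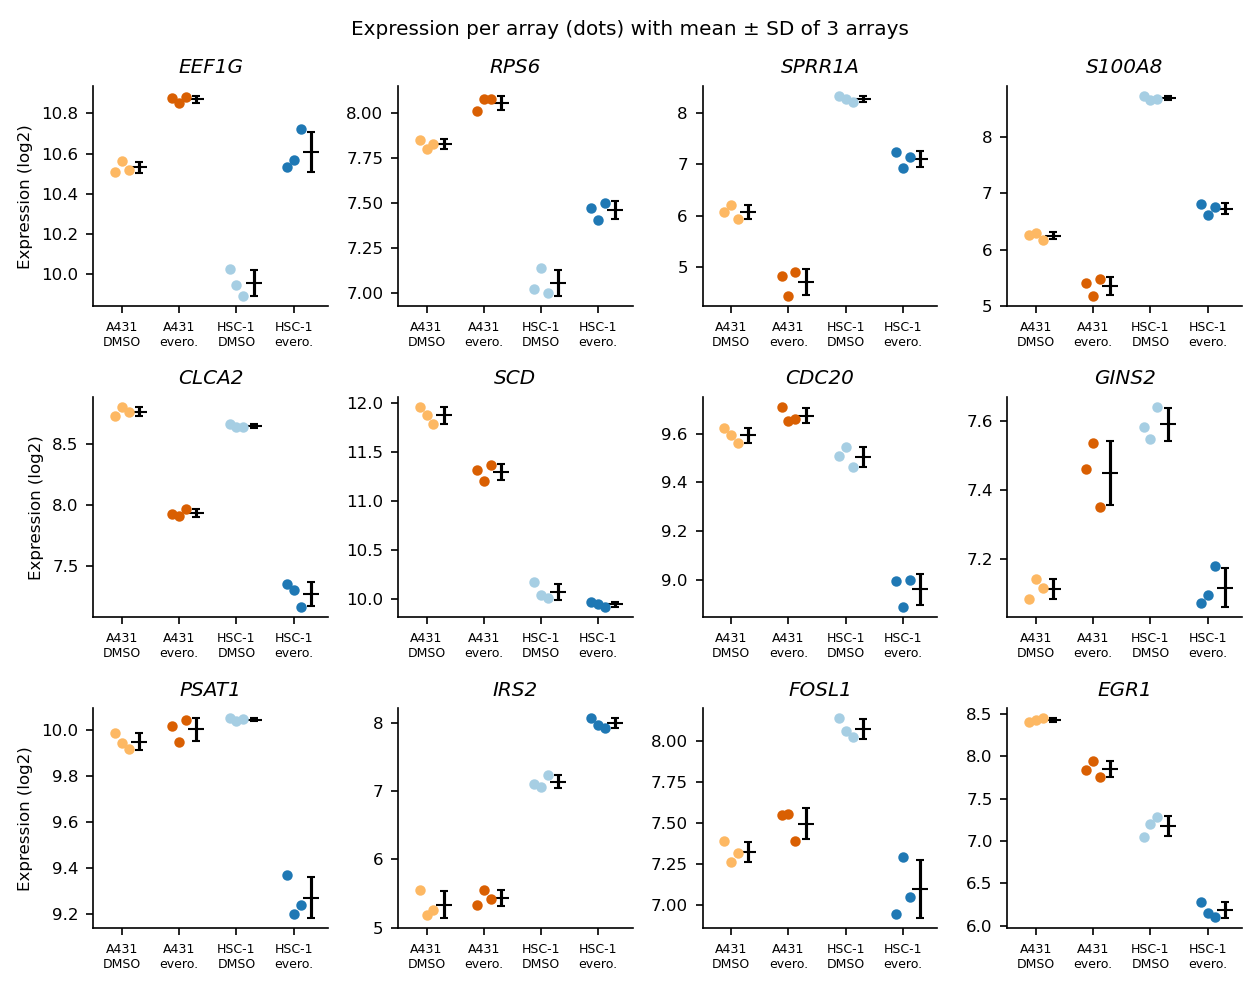
Each panel shows the log2 expression of 1 gene on the 12 arrays, as dots by group, with the mean and SD of 3 arrays beside them, and the y axes do not start at 0. EEF1G and RPS6 are higher and SPRR1A, S100A8 and EGR1 lower on the everolimus arrays of both lines, while CDC20, PSAT1 and FOSL1 are lower on those of HSC-1, and the effect on GINS2 differs between the lines by -0.81.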

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

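The results below differ between the lines by the test of the difference itself, or lie in probe sets without a gene name here. The look at which splits kept the real treatment arrangement of a line was chosen only after the split counts were seen.

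Past the threshold for the difference between the lines were 1118 genes, and 11 lists with camera, whose medians (HSC-1 effect minus A431 effect) were -0.36 for G2/M and mitosis, -0.34 for G1/S and DNA replication, -0.35 for inflammatory cytokines, -0.29 for ribosome biogenesis, -0.26 for ERK output, -0.17 for nucleotide synthesis, -0.10 for amino acid response, 0.14 for fatty acid synthesis, 0.14 for lysosome and autophagy, 0.14 for receptor, IRS and FOXO feedback and 0.12 for basal keratinocyte and adhesion. With an estimated correlation 4 of these lists did not pass: fatty acid synthesis (adjusted p = 0.0769), nucleotide synthesis (0.168), amino acid response (0.0769) and lysosome and autophagy (0.0729). Of the 118 genes named by the rule, 78 passed this test, against 1118 of all 10613 genes tested. The rule picks genes with large changes, some of them by this same test, so the higher share was built in.

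Higher in HSC-1 relative to A431, on the log2 scale, were PIGR 1.76, MIR3671 1.72, F2RL2 1.34, GPR15LG 1.31, VGLL1 1.30, AOC1 1.23, KLK13 1.12, CREBRF 1.1, MXRA5 1.08, KRT13 1.03, MIR23B 1.01, ACSL1 0.97, KRT4 0.96, TXNIP 0.85, IRS2 0.75, TPP1 0.61, PSAP 0.53, FASN 0.52, FGFR2 0.50, NOP53 0.48, CTSD 0.46, SCD 0.45, ACSS2 0.42, KRT15 0.40, BCAM 0.40, FNIP1 0.39, THBS1 0.35, EEF1G 0.31, SREBF1 0.30, CCND1 0.26 (a call lost without the intensity trend, adjusted p = 0.0505, in a range from 0.0022), RPL10 0.25, EIF4B 0.22, DDIT4 0.19 and EEF2 0.16.

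Among these and the values that follow, PIGR lay below the array median on all 6 HSC-1 arrays, MMP1, STC1, LOC440895 and EDN1 on all 6 A431 arrays, and KLK13 and PTGIS on 5 of 6 HSC-1 arrays, so the sizes of their differences depend on the background. Lower in HSC-1 relative to A431 were LAPTM5 -1.97, MMP1 -1.59, STC1 -1.29, LOC440895 -1.25, SNAR-D -1.16, FOSL1 -1.15, S100A8 -1.08, HBEGF -0.92, ICAM1 -0.91, S100A9 -0.91, IER3 -0.89, AMTN -0.86, MMP13 -0.85, PSAT1 -0.83, GINS2 -0.81, GNE -0.77, MCM10 -0.70, LYAR -0.67, PTGIS -0.63, CDC20 -0.62, AMIGO2 -0.61, MELTF -0.59, TTN -0.57, ELOVL6 -0.56, CTPS1 -0.56, IL1RN -0.55, CLCA2 -0.55, LCN2 -0.55, CDC6 -0.55, TNC -0.52, EDN1 -0.52, PLK1 -0.50, CCNA2 -0.49, RRM2 -0.48, ASNS -0.48, EIF4EBP1 -0.48, NIP7 -0.47, SHMT2 -0.46, CCNB1 -0.46, CCNE1 -0.43, EGR1 -0.42, NOP2 -0.40, MKI67 -0.40 and GPX2 -0.28.

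The lower cell cycle transcripts in HSC-1, without a fall in A431, were weighed against a single array and against an overall smaller response in A431. At the preset correlation, leaving out each of the 12 arrays left the camera adjusted p of the G2/M difference at 3.1e-19 or below. This argues against a single array at that setting. With an estimated correlation the full fit gave a camera adjusted p of 0.0157, and no array was left out there. Over the 48 cell cycle genes that fell in HSC-1, the slope of A431 on HSC-1 differences was -0.197 (95% bootstrap interval -0.280 to -0.124). It was 0.185 (0.139 to 0.230) over the 1150 other genes that fell there. These intervals resample genes, which are not independent replicates, and leave out the spread between arrays. The slopes differed in sign on these arrays, which leans against a uniformly smaller A431 response but does not exclude it. A line-specific effect of everolimus on proliferation may explain the difference, as a hypothesis found on these data; serum, cell density and growth rate at 72 h were not tested.

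Other splits of the same arrays gave these counts. For A431 the real split gave 714 genes and 10 lists, and the highest other of the 10 splits 1 gene and 5 lists. For HSC-1 these were 1977 genes and 12 lists against 0 and 5, and for the lines in DMSO 6303 genes and 5 lists against 0 and 2. A total of 10 splits is too few for a share under 5%. Camera at the preset correlation thus passed up to 5 lists in splits where at most 1 gene passed. Each other split still sets 2 arrays of a group against 1, so whether those passes are false cannot be told. A list that passed at the preset correlation alone is therefore weak evidence. For the difference between the lines, 1 of 100 splits, the real one, gave as many as 1118 genes, with 829 the highest other. This share is under 5%, which argues only against arrays without any everolimus effect. The split with 829 kept the real treatment arrangement of HSC-1, and the 80 splits that kept neither line's arrangement gave 0 genes. Breaking a line's arrangement removes its effect, so these splits do not test whether the effects of the lines are equal. For genes changed alike in both lines, 1 of 100 splits gave as many as 219, with 0 the highest other. Each other split breaks the arrangement of at least 1 line, which in the splits of each line left at most 1 gene, so this count adds nothing to those. For the 11 lists of the difference, 7 of 100 splits gave as many and the highest other gave 15, a share not under 5%. The 6 other splits among those 7 all kept the real treatment arrangement of HSC-1, and the 80 splits that kept neither line's arrangement gave at most 9 lists. Those 6 splits hold the HSC-1 effect, so they neither exclude chance for that number of lists nor show it.

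Among 17588 tested probe sets without a gene name here, which enter no comparison of genes, 321 changed in A431 and 1482 in HSC-1 with the same limma model, 163 and 913 of them upward, against 2123 and 3645 with an unadjusted p under 0.05.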

How the results depend on the processing

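The alternatives below were planned together with the comparisons. Of 185 gene results chosen by the rule, 167 kept their side of the threshold and direction under each alternative run, as did 37 of 92 list results, and of 175 gene results past the threshold 0 changed sign. Without the intensity trend, 438 genes passed in A431 and 126 alike in both lines. At 1.5-fold, 66, 139, 228 and 2817 genes passed in A431, HSC-1, the difference between the lines and the DMSO comparison, and at an adjusted p of 0.01, 347, 1115 and 541 in A431, HSC-1 and the difference, fewer because the thresholds are stricter. With an estimated correlation, 4 lists passed in A431, 7 for the difference and 0 in DMSO, where camera at the preset correlation called 5, and fry, which does not compare a list with other genes, gave 19 in HSC-1 and 19 in DMSO. With 1 array left out, the count ran from 456 (without A431 DMSO replicate 2, and 458 without replicate 1) to 836 in A431, 1405 to 2032 in HSC-1, 879 to 1161 for the difference, 5922 to 6364 in DMSO and 151 to 252 alike in both lines. Among list medians past the threshold, 1 changed sign: translation factors in A431, from -0.0252 (without A431 everolimus replicate 3) to 0.0378. Another 56 sign changes, of 23 results, were in values near 0 that passed the threshold in neither setting. Without a level filter they were in A431 the medians of amino acid response (0.00109), mTOR pathway (-0.0116) and cytokines (-0.034), and for the difference mTOR pathway (0.0163) and EMT (-0.0507). With the stricter filter they were in A431 amino acid response (0.00109) and interferon (0.00416), for the difference glycolysis (0.00429) and in DMSO keratinocyte differentiation (0.057). With quantile normalization again they were in A431 amino acid response (0.00325) and interferon (0.0025), for the difference cholesterol synthesis (-0.00199), in DMSO nucleotide synthesis (0.0102) and simple epithelial markers (0.00244), and in HSC-1 EGFR (-0.00589). With median centring they were amino acid response in A431 (0.00507), cholesterol synthesis in HSC-1 (0.00929) and keratinocyte differentiation in DMSO (0.000767). With the mean of probe sets they were in A431 amino acid response (0.00609) and interferon (0.00416), EMT in HSC-1 (-0.0326) and for the difference (-0.00634), and keratinocyte differentiation in DMSO (0.057). With 1 array left out, the ranges that crossed 0 were in A431 amino acid response -0.0305 to 0.0296, ERK output -0.012 to 0.0994, mTOR pathway -0.0228 to 0.026, basal keratinocyte -0.0662 to 0.0212, cytokines -0.00483 to 0.0467, simple epithelial markers -0.015 to 0.0953, KRT5 -0.0662 to 0.0212 and EGFR -0.0518 to 0.0165. In HSC-1 they were translation factors -0.12 to 0.00477, cholesterol synthesis -0.0405 to 0.0229, mTOR pathway -0.0064 to 0.0509, EMT -0.0477 to 0.0239 and EGFR -0.00221 to 0.0247. For the difference they were cholesterol synthesis -0.00482 to 0.0516, glycolysis -0.0519 to 0.00700, mTOR pathway -0.0484 to 0.0184, EMT -0.0315 to 0.104 and EGFR -0.00228 to 0.066. In DMSO they were glycolysis -0.000956 to 0.0547, keratinocyte differentiation -0.0729 to 0.0402 and simple epithelial markers -0.169 to 0.102. Except for the stricter thresholds, the cause was not tested. The replicate numbers did not pair the arrays: same-numbered arrays of a line had correlated deviations of -0.155 to 0.0181 over 6 pairs, 0 above 0.1, and 1 of 6 correlated best with its own number. With a replicate block, 477, 1611, 807 and 6212 genes passed in the 4 comparisons and 153 alike in both lines. A fit on 6 arrays was not planned for the difference between the lines. The number of arrays limits the precision, and signal over background could not be judged without detection values.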

Other observations

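The kallikrein, FOXO-linked and snaR lists below, the tests of keratinocyte differentiation in each line apart, by median and by count, and the test of dilution by other cells were chosen only after the results were seen, and the members that prompted a list are named with it. The other tests were planned before the result they measure.

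The list of the kallikrein protease family, prompted by KLK13, KLK9, KLK10 and KLK6 and sharing members with the differentiation list, is not independent evidence of its direction. Of 14 tested, 6 fell and 1 rose in A431 and 5 fell and 0 rose in HSC-1, and the others did not pass. KLK9 fell by 0.36 in A431 and 1.14 in HSC-1, KLK10 by 0.31 and 0.68, and KLK7 by 0.48 and 0.35, while KLK6 rose by 0.20 in A431 and fell by 0.69 in HSC-1. Of 631 long noncoding RNAs tested, 52 rose and 18 fell in HSC-1, and 4 rose and 8 fell in A431. Of 442 microRNA genes, 29 rose and 6 fell in HSC-1, and of 261 transcribed pseudogenes 35 rose and 6 fell, while 648 protein-coding genes rose and 1162 fell. Probe sets without a gene name leaned upward in HSC-1 too, 913 of 1482.

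Genes linked in the literature to FOXO factors and starvation, a list prompted by KLHL24, FBXO32, TXNIP, CALCOCO1, TCP11L2 and CREBRF, rose in 8 of 11 in HSC-1 with 0 falling, and in A431 3 fell and 0 rose, so the list is not independent evidence of its direction. KLHL24 rose by 1.04 in HSC-1, TCP11L2 by 0.84 and FBXO32 by 0.63. Of the 5 members that did not prompt it, CCNG2 (0.46) and YPEL3 (0.40) rose, and SESN3 (-0.09), KLF9 (0.16) and PINK1 (-0.15) did not pass. The difference between the lines was higher in 7 of 11 and lower in 0.

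Ribosomal protein transcripts rose in both lines. Among 10000 random lists matched on level, their median lay at percentile 100 in both lines, and again at percentile 100 when gene length was matched too, which argues against a joint shift of abundant or of short genes. A candidate explanation is an effect on transcripts with a terminal oligopyrimidine tract, whose translation mTOR controls: snoRNA host genes, which carry such a tract, had medians at percentile 98.6 in A431 and 99.85 in HSC-1 among level-matched lists. Of 7 tested, SNHG8 (0.22) alone rose in A431 and 4 rose in HSC-1, with 0 falling, while GAS5 differed by 0.22 in A431 (limma adjusted p = 0.0540) and rose by 0.25 in HSC-1, where SNHG15 (-0.08) did not pass, these 3 chosen after their values were seen. The random lists hold unrelated genes, so genes that vary together reach such percentiles more readily. For the host genes they were matched on level and not on RNA type. Of 631 long noncoding RNAs tested, 52 rose and 18 fell in HSC-1, and 4 rose and 8 fell in A431. The HSC-1 percentile may therefore reflect the RNA type of the host genes. Whether stability or synthesis differed was not tested.

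Lower keratinocyte differentiation transcripts were weighed against a joint shift of genes of the same level and against cells of another type. The test planned beforehand required the median to lie below the 2.5th percentile of level-matched lists in both lines; it lay at percentile 0 in A431 and 3.47 in HSC-1, so by that test a shift of genes of this level was not excluded for both lines. Taken apart, the A431 median argues against it there, while in HSC-1 the number of falling members, 10 against a random median of 4, lay at percentile 99.84, and since the median and this later count disagree, the level shift may still account for part of the HSC-1 pattern. Markers of fibroblasts, melanocytes, leukocytes and endothelium, 18 with a probe set, most of them low and CD68 (9.25) and SOX10 (5.66) the most abundant, had an upper 95% bound of 0.052 for their median difference, but 10 lay below the level filter and a median over 4 types cannot show a rise of 1 type, so that planned bound excludes nothing. Dilution by cells lacking these transcripts would lower them by 1 amount. Of the 15 more abundant members, 10 in A431 and 9 in HSC-1 had intervals above the median of the members that fell (-0.57 and -0.75). Only 5 and 2 of these had fallen themselves, and of the 15 members 1 rose in A431 and 4 in HSC-1. That median was set by the members that fell, so members that did not fall lie above it readily, and the counts cannot decide on dilution. The 7 tested basal keratinocyte and adhesion genes had medians of -0.02 in A431 and 0.09 in HSC-1. In A431 2 of them fell and 2 rose, and in HSC-1 1 fell and 2 rose. Dilution by cells that also lack these basal transcripts would lower them too. The values therefore argue against such cells as the whole cause. Dilution as part of the cause, or by cells that share the basal transcripts, and an effect of everolimus on differentiation stay open.

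The snaR transcripts, short RNAs made by RNA polymerase III and prompted by SNAR-B1, fell in 5 of 8 in HSC-1, and 1 fell in A431, but near-identical copies may share signal. The hypothesis that other transcripts of this polymerase fall too was not borne out: the median of 6 such transcripts in HSC-1 was 0.16, at percentile 98.62 among level-matched lists, with RPPH1 rising by 0.43 and VTRNA1-3 falling by 0.45.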
